A study of Mus musculus with 7 samples.

How the data were processed

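The samples were YFP+ Treg cells sorted from mLN of Rag-/- mice (strain background of the line, C57BL/6JRcc), with 4 WT and 3 Hpgd-deficient libraries as the titles label them. Per the labels' protocols, 10 ng of total RNA per sample was made into cDNA libraries with SmartSeq2, a protocol that amplifies full-length cDNA without molecular identifiers or strand information, sequenced on a NextSeq 500 and demultiplexed with bcl2fastq2 2.20. The submitters' processing notes name CASAVA 1.8, kallisto 0.44, Partek 6.6, R 3.3.1, DESeq2 without a version, and the genome build mm10, with no role or order. Whether genes were removed from the table is not given in the sources used here.

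The deposited values are a normalized expression signal per gene and library, made by the authors from reads. In each of the 7 libraries the lowest value was 1, and 100% of values minus 1 were whole multiples of 1 step per library, within 0.01 of a read. The values therefore hold an offset of 1, a gene without reads is listed as 1, and 1 read is worth between 0.703 (WT 4) and 1.84 (KO 3) in value. The inverse of the steps equalled median-of-ratios size factors recomputed from the recovered reads (0.909, 1.10, 0.884 and 1.42 for WT 1 to 4, and 1.32, 1.24 and 0.544 for KO 1 to 3). Normalized counts in the text are the deposited values minus 1. KO 3 had the fewest reads (4135733) and WT 4 the most (10622507), so low genes are least precise in KO 3. Reads amplified without molecular identifiers are not independent molecules, and intervals from reads cover counting error only.

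The comparison was fitted with limma 3.58.1 in R 4.3.3 on log2(normalized count + 1), with a trended eBayes prior, all 7 libraries and no covariate, and Benjamini-Hochberg adjustment at 0.05. Genes with a mean normalized count of at least 10 were tested (11787 of 15815). The plan named log2(value + 1). Since the deposited value already holds an offset of 1, this was read as 1 added to the normalized count, and adding 1 to the deposited value was run as an alternative. Hpgd, with a mean of 8.70, lay below the filter, and its estimate comes from the same fit to all 15815 genes. No count model was run, because the values as deposited are not counts. Voom on the recovered reads was run as an alternative.

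In total 38 gene lists were fixed before the data were examined, covering Treg and helper T cell programmes, prostaglandin and cAMP genes, metabolism, stress and cell cycle, the genes flanking Hpgd, and markers of other cell types. The 34 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists, beside camera with an estimated correlation and fry. The file writes a dot for a hyphen and gives mitochondrial genes without a prefix, and list names were matched to these spellings after the gene names had been seen. The beta globin gene listed as Hbb-b1 matched no list entry and is named separately. Gene coordinates are from GENCODE M21 (GRCm38, the assembly of mm10), in which 15595 of 15815 symbols were found. The lists hold 733 genes of the table, 54 of them in 2 or more lists.

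Genes were named by a rule fixed before the data were examined. It always names 9 genes (Hpgd, Foxp3, Il2ra, Ctla4, Ikzf2, Il10, Ptger2, Ptger4 and Pparg). It then takes up to 10 passing genes per direction whose groups do not overlap, by fold change. Where fewer than 8 pass, it fills up to 8 with the smallest unadjusted p among tested genes with non-overlapping groups and an absolute log2 fold change of at least 0.58, named as not passing. It adds up to 4 members of each called list in the list's direction, 2 members of each uncalled T cell or prostaglandin list by p, and the 2 most abundant members of each list of another cell type. Predicted genes, clone names, pseudogenes and antigen receptor segments are counted but not named. The rule gave 77 genes, of which 1 is not reported, and genes named outside it are marked in the text.

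Group separation was tested on principal components and Euclidean distances, and spread on standard deviations per gene, by exact permutation over all 35 splits of the libraries into 4 and 3. Library pairs were checked for duplicates with a chi-square on recovered reads. The smallest value per degree of freedom was 12.8, so no pair agreed within sampling noise. The fitting code was tested on simulated data, drawn from the means and dispersions of the 11787 tested genes with 200 genes changed in each of 10 simulations. It made 3.4 false calls per simulation, and camera called 0.1 lists per simulation where no list was changed. Genes were drawn independently of each other, so these rates do not carry over to correlated genes. The other splits of the real libraries called a median of 6.5 lists. Alternatives were other pseudocounts, scalings, filters and priors, array weights, the replicate number as a block, and leaving out each library in turn.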

Results

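The series holds 7 RNA-seq libraries from mouse regulatory T (Treg) cells, the CD4 T cells that restrain immune responses and depend on the transcription factor Foxp3. Rag-/- hosts, which lack T and B cells of their own, had received naive T cells and unmarked Treg cells, both WT, together with a YFP-marked Treg population. In 4 libraries (WT 1 to 4) the marked Treg cells were WT, and in 3 libraries (KO 1 to 3) they lacked Hpgd. The YFP+ cells were sorted from mesenteric lymph nodes (mLN) 8 weeks after transfer. The gene table lists 15815 genes. Reads behind it numbered 6519725, 8801234, 6129064 and 10622507 in WT 1 to 4, and 9501939, 8919815 and 4135733 in KO 1 to 3. Genes with at least 1 read ranged from 13557 in KO 3 to 15201 in KO 2. The labels do not say that each library came from a separate host, so p-values measure the spread between these samples, part of which can be technical. Levels below are normalized counts, given as mean ± SD. Fold changes are on the log2(normalized count + 1) scale, KO against WT. They compare means of log2 values and need not equal the ratio of the levels. For low genes the added 1 can understate the change. A library at 0 can also make the fold change larger than the ratio of the levels, as for Il10.

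The first question was whether the deleted gene was lower in the libraries labelled KO. Hpgd encodes the enzyme that oxidises and inactivates prostaglandins (mm10, chromosome 8, 56294585 to 56321043, plus strand; protein-coding, ENSMUSG00000031613.9). Its level was 13.0 ± 4.08 (SD, n = 4) in WT and 2.90 ± 2.41 (SD, n = 3) in KO. The WT libraries lay at 18.7, 9.96, 10.2 and 13.4, and the KO libraries at 0.759, 2.42 and 5.52, so the groups did not overlap. These levels rest on 56 reads in the 4 WT libraries and 7 reads in the 3 KO libraries, a ratio of 0.174 with a 95% exact Poisson interval of 0.0670 to 0.383 for counting error alone. The log2 fold change was -2.01 (SE 0.79). The exact two-sided permutation p was 0.0286, the smallest that 35 splits of 7 libraries can give. The unadjusted p of the limma fit was 0.0228, and after adjustment over all listed genes Hpgd did not pass (adjusted p = 1.00 in limma). Without WT 1, KO 1 or KO 2 the unadjusted limma p rose to 0.0599, 0.107 and 0.0514, with log2 fold changes of -1.83, -1.53 and -2.01. Reads from exons outside the deleted part would still be counted for Hpgd, and which exons were deleted is not given in the sources used here. Of 9 tested genes that flank Hpgd on the chromosome, 6 had higher and 3 lower estimates in KO, with no list shift (camera adjusted p = 0.245).

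**Figure D1:**
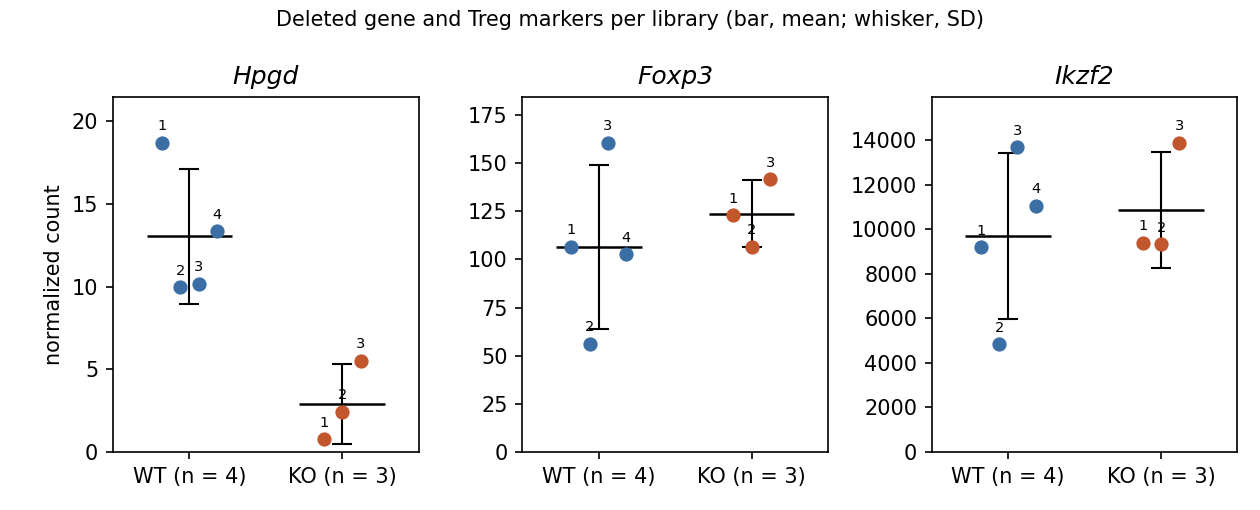
Normalized counts (vertical axes, from 0) of Hpgd, Foxp3 and Ikzf2 in WT (blue, n = 4) and KO (orange, n = 3) libraries. Points are libraries with their replicate number, horizontal bars are means and whiskers are SDs. Hpgd lies between 9.96 and 18.7 in WT and between 0.759 and 5.52 in KO, while the Foxp3 and Ikzf2 ranges overlap.

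Most Treg cell identity genes were abundant in both genotypes, with 14 of 20 above a mean of 1000 normalized counts. Foxp3 itself (mm10, chromosome X, 7573644 to 7595245) was at 107 ± 42.7 (SD, n = 4) in WT and 124 ± 17.5 (SD, n = 3) in KO, with a log2 fold change of 0.30 (SE 0.37; 95% interval -0.51 to 1.10; limma adjusted p = 1.00). This sign depended on WT 2 and KO 3, as the estimate without both was -0.08. Ikzf2, which encodes the Treg transcription factor Helios, was at 9687 ± 3721 in WT and 10860 ± 2609 in KO. The inhibitory receptor gene Ctla4 was at 5156 ± 1365 and 5597 ± 639, and the IL-2 receptor alpha chain gene Il2ra at 4503 ± 875 and 4564 ± 881. Over all 20 tested identity genes, 11 estimates were higher and 9 lower in KO, with a median log2 fold change of 0.01 (camera adjusted p = 0.879). Without both WT 2 and KO 3 the list was called higher in KO (camera adjusted p = 0.0341), while with an estimated correlation in all 7 libraries it was not (adjusted p = 0.969). The members with the smallest p were Nrp1 (log2 fold change 0.28, SE 0.23) and Il2rb (-0.23, SE 0.27). No identity gene passed over all genes or adjusted over the list alone. The level of the YFP reporter was not analysed here.

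The main comparison asked which genes differed between Hpgd-deficient and WT Treg cells. None of 11787 tested genes passed an adjusted p of 0.05 in limma, and the smallest adjusted p was 0.189. At an unadjusted p under 0.05 there were 211 genes, 92 higher and 119 lower in KO, where 589 would be expected by chance. The voom fit on recovered reads also passed 0 genes, with 184 at an unadjusted p under 0.05. The 4 WT and 3 KO values did not overlap for 430 tested genes, 3.65% of them, against 5.71% by chance. Libraries of the same size were simulated with the mean dispersion of genes at a similar level. There limma recovered 3.8% of genes changed 1.5-fold, 34.2% of those changed 2-fold, 79.2% of those changed 4-fold and 89% of those changed 8-fold. The simulated genes varied independently of each other, without a structure shared between genes, so these shares need not hold for the real libraries. The median 95% interval of a tested gene extended 0.67 log2 units to either side of its estimate.

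The 3 genes nearest to passing, Hba-a1, Hbb-b1 and Hba-a2, encode haemoglobin chains, made by red blood cells. All 4 globin genes named here had lower estimates in KO, but Hbb-bt was far from passing (limma adjusted p = 0.9996). The alpha chain gene Hba-a1 (mm10, chromosome 11, 32283511 to 32284465, plus strand) was at 194 ± 128 (SD, n = 4) in WT and 13.5 ± 10.6 (SD, n = 3) in KO, with a log2 fold change of -3.74 (SE 0.59; limma adjusted p = 0.189). Its neighbour Hba-a2 (chromosome 11, 32296489 to 32297298, plus strand) was at 867 ± 552 and 108 ± 53.2 (-2.90, SE 0.49; limma adjusted p = 0.201). The beta chain genes Hbb-bt (chromosome 7, 103812524 to 103813996, minus strand) and Hbb-b1 had log2 fold changes of -3.22 (SE 0.70) and -3.57 (SE 0.57), with levels of 72.4 ± 33.0 against 8.15 ± 6.17 and 408 ± 308 against 27.7 ± 12.6. For each of the 4 genes every WT library lay above every KO library, a condition of the naming rule that took them. Of the 4 tested genes on the erythroid list, 3 (Hba-a1, Hba-a2 and Hbb-bt) passed when adjusted over the list alone, and 0 passed over all genes. Without both WT 2 and KO 3, the libraries farthest from the rest on the first principal component, 4 genes passed over all genes, among them Hba-a1, Hba-a2 and Hbb-b1 (limma adjusted p = 0.0337, 0.0374 and 0.0403). With array weights 4 genes passed as well, among them these 3. Under the replicate block only these 3 passed (limma adjusted p = 0.00285, 1.83e-06 and 2.79e-05). The smallest limma adjusted p over all genes was 0.0938 without a filter on low genes, 0.0993 without WT 4 and 0.560 without KO 2. In 4 other settings the globin genes were far from passing. There the smallest adjusted p was 0.999 without the trended prior, 0.806 without WT 3 and 0.707 without KO 1, and with voom it was 1.00. The log2 fold change of Hba-a2 in these 4 settings lay between -3.04 and -2.44. Near-identical globin copies share sequence, so how reads were divided between Hba-a1 and Hba-a2, and between the beta genes, is uncertain.

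**Figure D2:**
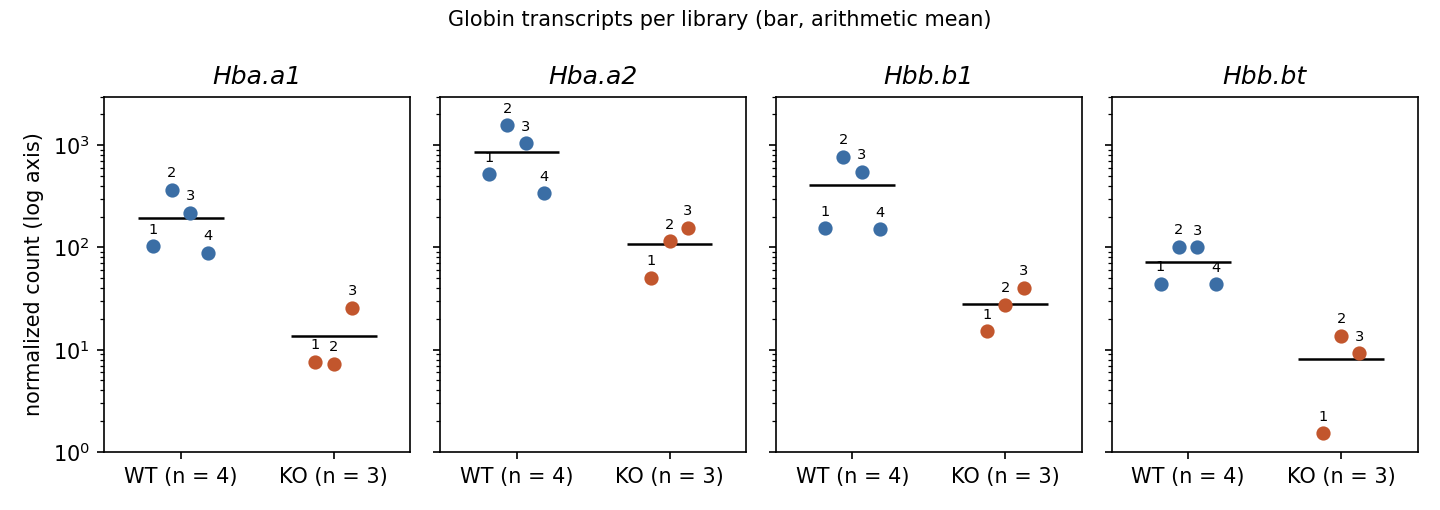
Normalized counts (log axis) of the globin genes Hba-a1, Hba-a2, Hbb-b1 and Hbb-bt, written with a dot in the panel titles as in the gene table, in WT (blue, n = 4) and KO (orange, n = 3) libraries. Points are libraries with their replicate number and bars are arithmetic means. Hba-a1 lies between 89.3 and 366 in WT and between 7.27 and 25.7 in KO.

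Among the other genes with groups that did not overlap, none of which passed, the naming rule took those with the smallest p. With lower estimates in KO it took Fbxl2, Map2, Bicdl1 and Spo11 beside the globin genes. Map2, a microtubule-binding protein gene best known from neurons, was at 55.7 ± 15.5 in WT and 13.1 ± 17.6 in KO. Bicdl1 was at 201 ± 23.0 and 108 ± 36.1. Spo11 was at 34.4 ± 17.3 and 6.22 ± 5.76. Fbxl2 had a mean of 37.7 ± 19.8 in WT, lay at 19.0 in KO 1 and was listed at 0 in KO 2 and KO 3. With higher estimates in KO it took Zfp658, Pla2g4a, Rapgef5, Zcchc2, Zmym2, Zfp566, Usp8 and Naip2. Among these Naip2, an inflammasome sensor gene, was at 303 ± 61.4 in WT and 466 ± 10.8 in KO, and the ubiquitin-specific protease gene Usp8 was at 433 ± 83.0 and 672 ± 117. The zinc finger genes Zmym2 and Zcchc2 were at 572 ± 89.6 and 918 ± 227, and at 397 ± 31.8 and 618 ± 116. Zfp658 was at 59.6 ± 12.5 and 142 ± 48.4, Zfp566 at 70.1 ± 8.60 and 160 ± 69.5, and the guanine nucleotide exchange factor gene Rapgef5 at 6.09 ± 4.46 and 43.9 ± 32.3.

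Genes of the prostaglandin and leukotriene pathway were of interest because Hpgd inactivates prostaglandins. The list also holds genes of leukotriene synthesis. The 17 tested members had 12 higher and 5 lower estimates in KO, with a median log2 fold change of 0.14. The list was not called (camera adjusted p = 0.142; adjusted p = 0.572 with an estimated correlation), and 0 members passed over all genes or adjusted over the list alone. It was called higher in KO with array weights (camera adjusted p = 0.0266) and without WT 2 (0.0483). The prostaglandin receptor genes Ptger4 and Ptger2, whose products raise cAMP, were at 1081 ± 211 and 357 ± 41.8 in WT and at 950.0 ± 113 and 386 ± 13.6 in KO. Pla2g4a, which encodes the cytosolic phospholipase that releases arachidonic acid, had the smallest p of the list. It was at 2.21 ± 3.72 in WT and 27.9 ± 14.7 in KO (log2 fold change 3.68, SE 1.16; limma adjusted p = 1.00). Alox5ap, needed for leukotriene synthesis, was at 10.7 ± 7.63 and 25.6 ± 9.61. The 24 genes of the cAMP and CREB response split into 11 higher and 13 lower estimates (camera adjusted p = 0.879), with Fosl2 at 123 ± 37.0 and 191 ± 6.44 and Rgs2 at 380 ± 176 and 522 ± 148.

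Suppressive effector genes were tested next. Of 24 members 16 had higher and 8 lower estimates in KO (median log2 fold change 0.11, camera adjusted p = 0.390). Il10, an anti-inflammatory cytokine gene, was at 28.7 ± 31.3 in WT and 93.7 ± 79.3 in KO, with library values from 0 to 69.6 and from 24.3 to 180 (log2 fold change 2.48, 95% interval -0.12 to 5.08; limma adjusted p = 1.00). The costimulatory receptor gene Icos was at 5480 ± 1070 and 6717 ± 622. The list of PPARg and adipose tissue Treg genes had 11 higher and 12 lower estimates (median 0.00, camera adjusted p = 0.593). Pparg was read at 26.4 in WT 1 and listed at 0 in the other 3 WT libraries, and lay at 5.31, 1.62 and 36.8 in KO. Cpt1a, the rate-limiting enzyme gene of mitochondrial fatty acid import, was at 702 ± 92.9 in WT and 968 ± 56.7 in KO with groups that did not overlap, and the lipid droplet gene Plin2 at 277 ± 92.6 and 406 ± 150. Neither passed the limma test.

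Of the Th1, Th2, Th17 and naive T cell lists only the Th17 list was called. It was called higher in KO (camera adjusted p = 0.00497; 7 of 9 tested members with higher estimates, median log2 fold change 0.32), and the call was lost with an estimated correlation (adjusted p = 0.450). That correlation was -0.0406, below the preset 0.01, so a higher correlation between members did not end the call. The list mean was 7.54 in WT and 8.30 in KO on the log2 scale, with every KO library above every WT library (exact permutation p = 0.0286, the smallest possible). This p is not adjusted over the lists, and the erythroid list reached it as well. In the uncalled naive and lymphoid homing list every KO library also lay above every WT library (exact permutation p = 0.0571). Within the Th17 list Il23r and Il1r1, cytokine receptor genes of Th17 cells, had the smallest p. Il23r was at 1.02 ± 1.61 and 26.0 ± 24.7, and Il1r1 at 39.3 ± 21.0 and 115 ± 72.5. Il23r was near the floor, with 0, 0, 3 and 1 reads in WT 1 to 4 and 7, 24 and 29 in KO 1 to 3. Its log2 fold change of 3.53 lifts the mean over the members to 0.75, against the median of 0.32. The closest libraries of the 2 groups were WT 1 and KO 1, with list means of 7.74 and 8.03. The separation of the groups on the list mean can therefore rest on Il23r. The chemokine receptor gene Ccr6 was at 395 ± 85.4 and 503 ± 57.7. No member passed over all genes or adjusted over the list alone. Leaving out both WT 2 and KO 3 ended the call (camera adjusted p = 0.0931), with a difference of the list means of 0.58 against 0.75 in all 7 libraries and groups that still did not overlap. The Th1 list (10 of 14 estimates lower, camera adjusted p = 0.245) and the Th2 list (6 of 8 higher, camera adjusted p = 0.452) were not called. With array weights the Th1 list was called lower (camera adjusted p = 0.0266; adjusted p = 0.876 with an estimated correlation and equal weights). The Th1 members with the smallest p were Eomes at 37.6 ± 16.4 and 20.5 ± 18.1, and Il12rb2 at 17.4 ± 9.73 and 8.19 ± 10.3. The Th2 members were Ccr3 and Stat6, with log2 fold changes of 0.58 (SE 0.58) and 0.21 (SE 0.21). Naive and lymphoid homing genes had 11 of 17 estimates higher (camera adjusted p = 0.139), led by Igfbp4 (0.80, SE 0.38) and Satb1 (0.50, SE 0.26).

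Ribosomal protein transcripts gave the smallest p among the lists. Of 81 tested members 79 had lower estimates in KO, with a median log2 fold change of -0.32 (camera adjusted p = 3.17e-23). With an estimated correlation, which was 0.754 between members, the call was lost (adjusted p = 0.667). Rplp2 was at 2984 ± 971 in WT and 1752 ± 259 in KO, Rps29 at 4583 ± 1799 and 2592 ± 253, Rpl37 at 2004 ± 699 and 1228 ± 156, and Rps21 at 1482 ± 418 and 884 ± 271. None passed the limma test, alone or adjusted over the list alone. WT 2 stood apart: ribosomal protein genes took 7.76% of its reads and 4.49% to 5.65% of those of the other libraries. Without WT 2 the list median was -0.14, with 61 of 81 members lower (camera adjusted p = 5.27e-08). The list means of WT and KO then overlapped. Ribosomal protein genes have many processed copies in the genome, so single members are uncertain.

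Oxidative phosphorylation and interferon response genes were also called lower in KO, and both calls depended on WT 2. The oxidative phosphorylation list had 31 of 39 estimates lower (median log2 fold change -0.13, camera adjusted p = 0.00497; adjusted p = 0.876 with an estimated correlation). Its members with the smallest p, Cox7c, Atp5d, Ndufa2 and Cox6c, had log2 fold changes from -0.31 to -0.40. The interferon response list had 27 of 37 estimates lower (median -0.17, camera adjusted p = 0.0458; adjusted p = 0.876 with an estimated correlation). Ifi27l2a was at 5388 ± 3466 and 2955 ± 1171, Irf7 at 518 ± 289 and 313 ± 98.1, Ifit3 at 625 ± 448 and 340 ± 203, and Ifi44 at 56.3 ± 62.6 and 20.7 ± 21.3. WT 2 held the highest value of each of these 4 genes. Without WT 2 the camera adjusted p was 0.720 for oxidative phosphorylation, whose direction then turned, and 0.937 for the interferon response. Leaving out KO 1 or KO 2 also ended the first call (adjusted p = 0.0803 and 0.139), and leaving out WT 1, KO 2 or KO 3 the second (0.0793, 0.529 and 0.187). The difference of the oxidative phosphorylation list means was -0.13 in all 7 libraries, -0.13 without KO 1, -0.11 without KO 2 and 0.02 without WT 2. For the interferon response it was -0.22 in all 7 libraries, -0.20 without WT 1, -0.15 without KO 2, -0.14 without KO 3 and -0.07 without WT 2.

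The cell cycle list was called higher in KO, a call that was lost with an estimated correlation. Of 42 members 32 had higher and 10 lower estimates, with a median log2 fold change of 0.27 (camera adjusted p = 0.00497; adjusted p = 0.531 with an estimated correlation). The estimated correlation was 0.0298, low beside the 0.754 of the ribosomal protein list. The proliferation marker gene Mki67 was at 490 ± 246 in WT and 748 ± 76.1 in KO, the topoisomerase gene Top2a at 477 ± 76.9 and 639 ± 76.6, Kif2c at 22.1 ± 9.33 and 60.7 ± 33.5, and Tpx2 at 81.0 ± 26.8 and 123 ± 25.3. Mki67 was at 124 in WT 2 and at 581 to 656 in the other WT libraries. No member passed over all genes or adjusted over the list alone, and the list mean had an exact permutation p of 0.0571. Leaving out WT 3 ended the call (camera adjusted p = 0.0773), with a difference of the list means of 0.14 against 0.18 in all 7 libraries.

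The 29 other tested lists had camera adjusted p from 0.0512 to 0.992. The lowest was that of the mitochondrial genome, with 11 of 13 estimates higher in KO, and this direction rested on WT 2. Its list mean was 12.0 in WT 2, 13.1 to 13.6 in the other WT libraries and 13.1 to 13.5 in KO, and without WT 2 the direction turned (camera adjusted p = 0.720). The list was called in 8 of 22 settings, among them those without WT 3, WT 4 or KO 1 (camera adjusted p = 9.04e-04, 0.00392 and 0.00710), and its adjusted p was 0.876 with an estimated correlation in all 7 libraries. The other lists include histones (17 of 28 lower, 0.0581), immediate early and handling stress genes (15 of 23 higher, 0.142), the unfolded protein response (13 of 20 higher, 0.267), T cell receptor activation (14 of 22 lower, 0.382), the IL-2 and STAT5 response and NF-kB genes (both 0.593), and Tfh genes (0.992). The immediate early and handling stress list also holds heat shock genes, so its shift cannot be assigned to immediate early genes. Glycolysis, fatty acid oxidation, sterol synthesis and apoptosis lists each had an adjusted p of 0.879. Without WT 2, glycolysis (camera adjusted p = 0.0208), the unfolded protein response (0.0290) and the immediate early and handling stress list (0.0200) were called higher in KO, and without both WT 2 and KO 3 they were called as well (6.18e-05, 0.00320 and 0.00367). With an estimated correlation in all 7 libraries none of these 3 was called (adjusted p = 0.979, 0.876 and 0.876). The immediate early and handling stress list and histones were each called in 6 of 22 settings, and the adjusted p of histones with an estimated correlation was 0.531. The 4 Y-linked genes, too few to test, had higher estimates in KO, but the difference of the list means was 0.18 with WT 2 and -0.19 without it. In place of 5 called lists there were 8 without WT 2 and 3 without KO 2.

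**Figure D3:**
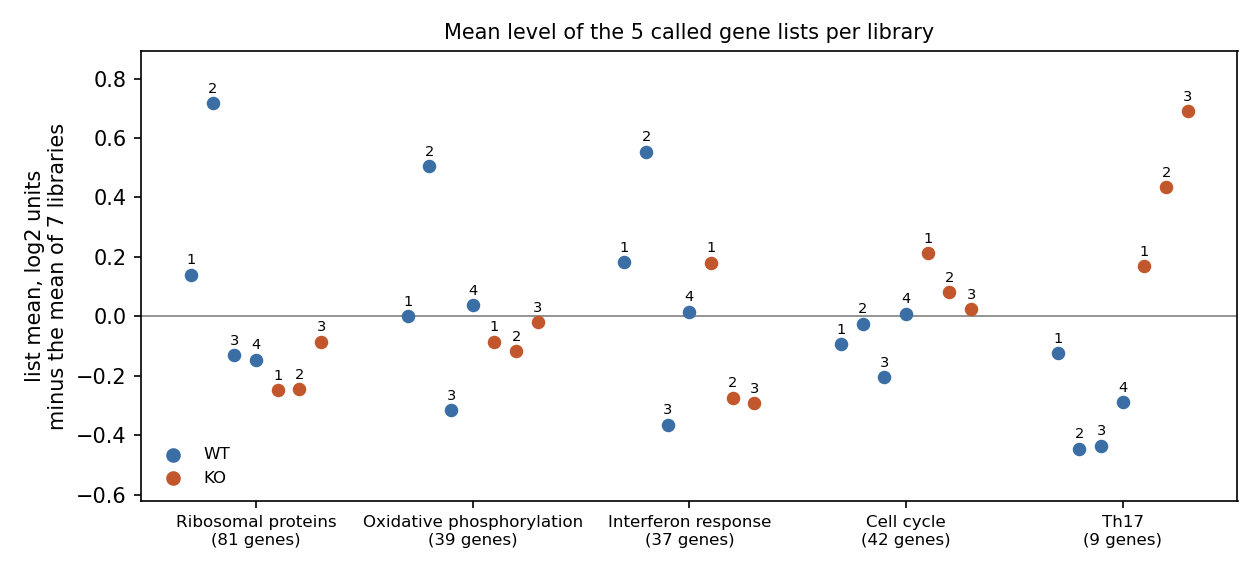
Mean log2(normalized count + 1) of the 5 called gene lists in each library, minus the mean of the 7 libraries (vertical axis, log2 units). Points are libraries, blue for WT and orange for KO, with their replicate number. WT 2 is the highest library for ribosomal proteins, oxidative phosphorylation and interferon response, and only for the Th17 and cell cycle lists do all KO points lie above all WT points.

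Markers of other cell types in the sort were checked. Of these lists, those with 5 or more tested members were not called: CD8 T cells (camera adjusted p = 0.114), NK cells and ILC (0.442), B cells (0.879), macrophages and monocytes (0.879), dendritic cells (0.879), neutrophils and mast cells (0.879) and conventional CD4 T cells (0.879). For B and conventional CD4 T cells the mean log2 fold changes were positive while the medians and the test pointed down. Among their most abundant members, several are also expressed by activated or tissue Treg cells, such as Nkg7 (3238 ± 1636 in WT, 2458 ± 131 in KO), Il1rl1 (1112 ± 459 and 1340 ± 496) and Ccr2 (1238 ± 556 and 1747 ± 988). Ccl5 was at 1192 ± 577 and 687 ± 151, Gzma at 773 ± 663 and 1029 ± 539, and Ctss at 5145 ± 848 and 5339 ± 495. The B cell receptor component gene Cd79b was at 496 ± 183 and 376 ± 52.8, Bank1 at 108 ± 24.8 and 104 ± 55.5, Cd8b1 at 96.6 ± 21.4 and 72.8 ± 49.0, and Crtam at 31.9 ± 32.5 and 55.9 ± 36.6. The antigen presentation gene Cd74 was at 4003 ± 2140 and 3523 ± 922, Cst3 at 1278 ± 484 and 1280 ± 173, Mmp9 at 79.6 ± 40.8 and 77.3 ± 38.2, and Edem2 at 716 ± 295 and 497 ± 278. The neutrophil gene S100a8 was at 471 in KO 1 and between 12.9 and 96.1 in the other libraries, and the plasma cell gene Jchain at 119 in KO 1 and between 3.68 and 21.5 elsewhere. The plasma cell and stromal lists had 2 and 3 tested members and were not tested, nor was the erythroid list with 4. In 4 settings in which it had 5 tested members, among them without WT 2 and without KO 1, the erythroid list was called lower in KO (camera adjusted p = 4.69e-09 and 6.21e-06). These calls use the preset correlation of 0.01, and no estimated correlation was run for this list. Most of its members are globin genes that vary together, so the calls can count the same difference more than once. Without WT 3 the macrophage and monocyte list was called lower (camera adjusted p = 0.0130; adjusted p = 0.979 with an estimated correlation in all 7 libraries). Pecam1 was at 305 ± 88.6 and 308 ± 73.4, and Col1a1 at 24.4 ± 5.19 and 22.0 ± 9.99.

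Genotype was not a main axis of variation over all tested genes. The first and second principal components held 35.1% and 25.0% of the variance, and WT 2 (PC1 score 81.9) and KO 3 (-61.0) formed the ends of the first. Exact permutation tests over 35 splits gave p = 0.457 for PC1 and p = 0.486 for PC2. Libraries of different genotype were no farther apart than libraries of the same genotype, with a between-minus-within distance of -0.04 log2 units (exact one-sided permutation p = 0.8). The median ratio of the KO to the WT standard deviation per gene was 0.752 (exact two-sided permutation p = 0.514). It was 1.05 without WT 2 and 0.444 without KO 3.

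**Figure D4:**
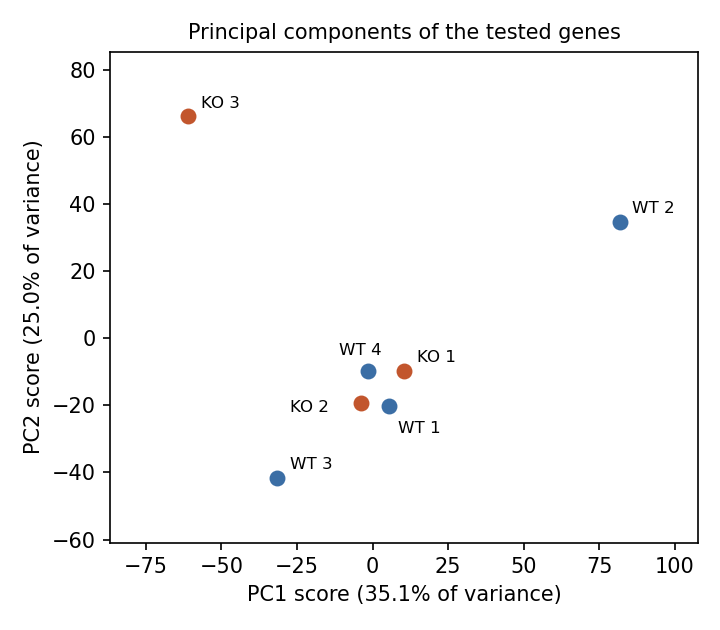
Scores of the 7 libraries on the first and second principal components of the log2 values of 11787 genes (axes in score units, with the share of variance). Blue points are WT and orange points are KO. WT 2, KO 3 and WT 3 lie apart, and WT 1, WT 4, KO 1 and KO 2 lie close together.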

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

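All 118 reported quantities with 4 WT values were searched for a WT library far from the other 3, measured by its gap to the nearest value as a share of the range. Chance picks about 5% of such groups, and 6 (5.08%) were picked, so the number is what chance gives. KO groups of 3 were not searched, and no explanation is offered for these values.

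Pparg was read in WT 1 alone among the WT libraries, at 4.78 on the log2 scale against 0 in the other 3 (gap share 1). Mki67 was lowest in WT 2, at 6.97 against 9.19 to 9.36 (gap share 0.927). Nrp1, a Treg surface receptor gene, was also lowest in WT 2, at 10.6 against 11.3 to 11.4 (gap share 0.844). The mean of the macrophage and monocyte list was lowest in WT 3, at 5.16 against 6.93 to 7.20 (gap share 0.868). The mean of the Th2 list was highest in WT 3, at 8.39 against 8.00 to 8.06 (gap share 0.840). Ptger4 was highest in WT 3, at 10.4 against 9.87 to 9.97 (gap share 0.830).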

How the results depend on the processing

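The voom fit, the pseudocount of 2 and the fit without WT 2 and KO 3 were chosen after seeing the data. The 2 fits meant for count tables were not run, since the deposited values are not counts. Median-of-ratios rescaling left the values almost as they were, because the authors' factors are of that kind, so it says nothing about stability. With 1 library left out, 20 or 15 splits remain and no permutation p can fall below 0.05.

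Genes passed in 3 of the alternative fits and in none of the others. Array weights passed 4 genes, and leaving out WT 2 and KO 3 passed 4, with Hba-a1, Hba-a2 and Hbb-b1 in both sets. Leaving out single libraries gave 0 to 0. The replicate block over replicates 1 to 3 passed 3 genes, these globin genes. The replicate numbers share only a number: same-numbered libraries had correlations of -0.01, -0.05 and 0.12 between their deviations. Under the block Hpgd had a log2 fold change of -1.98 with an unadjusted p of 0.0760, on 6 libraries. Its estimates without single libraries ran from -2.47 to -1.53. Foxp3 kept its sign without single libraries (0.03 to 0.53) and turned to -0.0757 without WT 2 and KO 3. The 75 other named genes were compared under 20 settings. Of 1476 comparisons 9 passed the threshold, in 3 genes, and 43 changed sign, in 21 genes, none of them called.

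The number of called lists was 5. It was 8 without a filter on low genes, 0 with an estimated correlation, 0 with fry, and 3 to 8 without single libraries. Adjusted p with an estimated correlation and with fry were 0.667 and 0.828 for ribosomal proteins, 0.450 and 0.301 for Th17, 0.531 and 0.485 for cell cycle, 0.876 and 0.980 for oxidative phosphorylation, and 0.876 and 0.980 for the interferon response. The interferon call also ended under quantile normalization (0.0841), array weights (0.0502), eBayes without trend (0.129) and a mean of at least 50 (0.0607). Without WT 2 and KO 3 the adjusted p was 0.0931 for Th17, 0.838 for oxidative phosphorylation and 0.507 for the interferon response, whose direction turned. Without single libraries adjusted p ran from 4.94e-32 to 5.27e-08 for ribosomal proteins, 1.03e-04 to 0.0491 for Th17, 1.46e-05 to 0.0773 for cell cycle, 2.26e-07 to 0.720 for oxidative phosphorylation and 1.95e-05 to 0.937 for the interferon response. Fewer libraries enter the fits without libraries. For the other settings the cause was not tested. Without single libraries the separation p ran from 0.600 to 1 and the spread ratio from 0.444 to 1.05, and with the 500 most variable genes the separation p was 0.514. Depth limits Hpgd, with 1 to 19 reads per library.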

Other observations

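The tests of the globin ratio and of ribosomal protein genes without WT 2 were chosen after their results had been seen. The genes in the next paragraph were chosen by level after their values had been seen.

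Levels of members of some lists are given here over both genotypes. Itgae, the integrin alpha chain gene that pairs with beta 7 and binds E-cadherin, was the most abundant member of the chemokine and adhesion receptor list at 12353 ± 2244 (SD over 7 libraries), followed by Selplg at 9337 ± 2567 and Itgb7 at 8265 ± 2149. Among chemokine receptor genes Cxcr3 led at 2651 ± 845, then Ccr2 at 1456 ± 744, and the small intestine homing receptor gene Ccr9 was at 860 ± 358. That list split into 12 higher and 9 lower estimates in KO (camera adjusted p = 0.475). Among lineage regulator genes Gata3 was at 2419 ± 413 and Tbx21 at 85.9 ± 45.3, while the cytokine genes Il17a (1.30 ± 1.71), Il4 (33.0 ± 7.66) and Ifng (70.5 ± 70.7) were low. The cytotoxic granule gene Gzmb was abundant and varied between libraries, from 1523 to 8192. The ectoenzyme genes Nt5e and Entpd1, which make adenosine, were at 3611 ± 658 and 647 ± 116. In the prostaglandin and leukotriene list the cyclooxygenase genes were near the floor, with Ptgs1 at 9.04 ± 6.97 and Ptgs2 at 2.39 ± 5.33, while Lta4h (1847 ± 158) and Ptges3 (1833 ± 556) led.

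The results were set against other splits of the 7 libraries into 4 and 3. For the 0 passing genes this says nothing, since all 35 splits reach a count of 0, and the highest of the others gave 1. At an unadjusted p under 0.05 the real split gave 211 genes, and 31 of the 35 splits gave as many, up to 1596. In 28 of the 35 splits at least 5 lists were called, the highest other split called 13, and ribosomal proteins were called in 32 splits. Chance can therefore not be excluded for the 5 lists or for the 211 genes. That other splits gave several times as many genes points to a structure of the samples that does not follow genotype, whose origin was not tested. With an estimated correlation 0 lists were called in each of the 35 splits.

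Each of the 4 globin genes was lower in every KO library than in every WT library, and a candidate explanation is red blood cell RNA from 1 source, as the YFP gate would remove whole red cells but not free RNA. The largest SD of a log2 ratio of another globin gene to Hba-a2 was 0.62 against 1.77 for Hba-a2 itself, which separates no explanations, since the group difference is part of the second SD. Red cell genes other than globin had a median log2 fold change of 0.0333 (SE 0.30), but only 1 of 9 had a mean of at least 10, so red cell RNA cannot be told apart from other causes. WT 2 and KO 3 as the cause are argued against by the median of the 4 genes, which was -3.36 without them and -3.40 with them. All 4 genes keep the groups apart in 2 of the 35 splits. Any gene with 7 distinct values does so in 2 splits, so this count cannot decide on chance. A difference between hosts or genotypes stays open, as untested.

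The ribosomal protein list was called lower in KO, and the call was lost with an estimated correlation (adjusted p = 0.667). Library WT 2 may account for part of this, since the median log2 fold change was -0.14 without WT 2 against -0.32 with it, though the list was still called at the preset correlation. Short transcripts were also enriched in WT 2: a doubling of transcript length went with a change of -0.29 log2 units in WT 2 and of 0.00 to 0.15 in the other libraries. In 1000 gene sets matched on length and expression, the medians had a median of -0.0907 and a lowest value of -0.15. Length was that of the longest annotated transcript, with a median of 1094 nucleotides for ribosomal protein genes and 1189 for matched genes. The longest transcript need not be the one expressed, so the matched sets cannot decide on transcript length as the cause. Without WT 2 the list means of WT and KO overlapped. On the log2 scale they were 11.74, 11.47 and 11.46 in WT 1, WT 3 and WT 4, and 11.35, 11.36 and 11.52 in KO 1 to 3. Of the remaining WT libraries only WT 1 lay above all KO libraries, while each lay above KO 1 and KO 2. Without both WT 2 and KO 3 the groups did not overlap, with a difference of the list means of -0.20. The list was then called at the preset correlation (camera adjusted p = 3.67e-12). Transcript length and a difference between genotypes stay open for the remainder.

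Library WT 3 held transcripts of the pancreas, noticed while the tables were read, among them Gcg at 110 normalized counts, Amy2a5 at 93.9, Cela2a at 83.7 and Clps at 72.4, against 6.46 or below in the other 6 libraries. Pancreatic tissue RNA in this sample may be the source, although the YFP gate would remove whole pancreatic cells but not free RNA. Of 18 further pancreatic genes in the table, 16 were highest in WT 3 (one-sided exact binomial p = 3.45e-12 against 1 in 7), among them Chgb, Pnlip and Ctrb1. This p treats the genes as independent. Transcripts of 1 tissue can enter a library together, so it does not measure chance. All listed genes, the first noticed ones included, held 611 reads in WT 3 and 311 in the other 6 libraries together. Gcg, Amy2a5, Cela2a and Clps, chosen after their values had been seen, held 97, 83, 74 and 64 of the WT 3 reads. The total is therefore not independent of that choice. The labels give no group that would separate WT 3 from the other WT libraries, so no biological explanation was tested.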
